A study of Chlamydomonas reinhardtii with 18 samples.

How the data were processed

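Polyadenylated RNA of Chlamydomonas reinhardtii strain CC-4532, a unicellular green alga, was sequenced on an Illumina HiSeq 2000, per the labels' protocols. Cells had been grown in acetate-containing TAP medium under continuous light of about 90 µmol photons per square metre and second at 24 °C. They were pelleted at 2500 g for 5 min, washed 2 times in TAP without Fe-EDTA and put into fresh TAP with 0 µM Fe-EDTA. The 18 samples fall into 9 groups of 2 cultures, taken before the wash, directly after it, at 5, 10 and 15 min, at 30 and 60 min, and at 120 and 240 min. The iron content of the medium before the wash is not given in the sources used here.

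The deposited table holds FPKM (fragments per kilobase of transcript scaled to the number of mapped fragments) for 17741 genes, with gene identifiers of annotation version v5.6 per the file headers. STAR 2.4.1 and Cuffdiff 2.0.2 are listed in the submitters' processing notes. How these tools scaled the libraries against each other, and whether strand was used, is not given in the sources used here. Each time point has a single FPKM column for its pair of cultures, so the authors combined the cultures before deposit. Another 9 columns of values belong to samples outside the 18 and were not used here.

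Because the cultures are combined, no value has a replicate error, and the planned linear models (limma), gene set tests, adjusted p-values, replicate block and leave-one-out fits were not run. Differences are described by size alone. A gene was counted when its values differed by at least 2-fold on the log2(FPKM + 1) scale. The pseudocount of 1 understates the change of weakly expressed genes. Folds printed beside single genes are plain ratios of FPKM, while counts and ranks use FPKM + 1. Genes with FPKM of 1 or more in at least 2 columns were kept, which left 12580 genes. As a guide to variation between samplings, the columns for 10 and 15 min differed with a robust SD of 0.168 on the log2 scale, and 7 genes differed by 2-fold or more. This pair was picked because it was the closest of the neighbouring time points, so its spread may understate the variation between other samplings. The other neighbouring pairs ran from 0.192 (5 and 10 min) to 0.435 (pre-wash and post-wash). Any real change between the samplings of a pair is part of its spread.

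Library depth is unknown. Ratios of the lowest values between neighbouring columns recurred in part, for example a log2 ratio of 0.70 from pre-wash to post-wash in 9 of 54 genes and of -0.17 from 60 to 120 min in 14 of 102 genes, but whole reads could not be recovered. Column sums ran from 631357 FPKM before the wash to 762490 at 10 min, and the 10 most abundant genes held 10.1% (60 min) to 13.2% (240 min) of the sum.

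A set of 24 gene lists, the contrasts, the rule for naming genes and the alternative settings were fixed before the data were examined. Some lists share genes by definition. The fermentation and acetate lists share ACK1, ACK2, PAT1 and PAT2, the copper-responsive and tetrapyrrole lists CPX1 and CRD1, and the iron assimilation and antioxidant lists MSD3. Symbols came from the deposited table, which gives 5186 genes a symbol. The RefSeq table of assembly Chlamydomonas_reinhardtii_v5.5 matched 17738 identifiers but gave no symbol other than locus tags, so it served to show which genes are neighbours and no coordinates are printed. In 7 cases a symbol matched a list but the deposited product named another protein, and these were left out of the lists, a check of products made after the data were examined. For each list the median log2 difference is given with its place among 10000 random lists of the same size matched on mean expression in 20 bins. That place describes these columns and is no test, since genes are not replicates and members of one pathway vary together.

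Named genes are all measured members of the iron assimilation list, up to 4 members of any other list with the largest differences in the contrast discussed, and the 10 (wash, 30 min, 240 min) or 3 (other times) genes with the largest differences each way that have a symbol and FPKM of 5 or more in at least 1 of the columns compared. Genes without a symbol are named only where they had the largest difference of a contrast, and not in each such contrast. At 5, 10 and 15 min a gene without a symbol lay furthest below post-wash and is not named. The parts of that rule that need a p-value or single replicates could not be applied.

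Alternatives were a pseudocount of 0.1, no filter on low values, FPKM of 5 or more in at least 2 columns, quantile normalization and median-of-ratios scaling. The counting step was tested on simulated data for 30 min against post-wash, on 11776 genes. Each simulated column got noise with an SD of 0.168, the robust SD of the difference between the 10 and 15 min columns. A simulated difference between 2 columns therefore varied more than that pair, and the SD was the same at all expression levels. The counting step found 100% of 100 genes planted at 4-fold and 72% of 100 planted at 2.5-fold. Folds were planted only in genes with FPKM of 5 or more post-wash, so these rates do not cover weaker genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.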

Results

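The transcriptome of Chlamydomonas CC-4532 was followed from before a wash into iron-free medium until 240 min after it, at 9 sampling points with 2 cultures each. The deposited FPKM give 1 value per gene and sampling point for both cultures together, so every value is the authors' combined value. No replicate error, test or p-value can be given, and depth is unknown. Differences of 2-fold or more are therefore reported by size, as higher or lower values. The number of genes with FPKM of 1 or more ranged from 11224 (15 min) to 11869 (120 min), and median-of-ratios scaling would have moved the columns by log2 factors between -0.040 and 0.038.

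The pre-wash and post-wash samples show what was different directly after the wash. Transcripts for fermentation, cilia, the CO2-concentrating mechanism and photoprotection were among those that were higher. In the fermentation and anoxia list, 8 of 13 measured genes were at least 2-fold higher after the wash and 0 lower, with a median log2 difference of 2.09, above all 10000 random lists. HYDG1 (Cre06.g296700), a hydrogenase maturation factor, was at 16.8 FPKM before and 328 after the wash, and HYDEF1, another maturation factor, at 1.81 and 37.5. HYDA1, which encodes an iron hydrogenase, was at 58.5 and 391 FPKM, and ADH1, an alcohol dehydrogenase of fermentation, at 28.8 and 190. Of 328 cilia genes, 179 were higher and 0 lower by 2-fold, with a median of 1.05. FAP138 (5.64 and 43.1 FPKM), FAP15 (11.8 and 72.9), FAP289 (6.2 and 37.0) and FAP129 (13.4 and 71.2), all flagellar associated proteins, differed most. AOX1, the mitochondrial alternative oxidase, was the only one of 73 respiratory chain genes 2-fold higher (19.7 and 129 FPKM), and the list median was 0.14, or -0.14 under quantile normalization.

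The CO2-concentrating list, of carbonic anhydrases and inorganic carbon transporters, had 4 of 13 measured genes 2-fold higher after the wash and 0 lower, with a median of 0.78, above all 10000 random lists. These were CCP2, NAR1.2, LCID (3.39 and 30.4 FPKM) and CCP1 (6.21 and 21.9). In the photoprotection list 4 of 10 genes were higher and 1 lower (median 0.57, percentile 98.79 of the random lists, but 0.28 under quantile normalization and 0.20 without the filter on low values), with ELI3 at 8.84 and 60.6 FPKM and LHCSR1 at 6.40 and 23.1.

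Among all genes with a symbol, PHX5 differed most by the wash, from 3.08 to 143 FPKM, and the unnamed gene Cre08.g372200 went from 45.4 to 1789 FPKM. PHX4 (0.685 and 31.9) and PHX15 (41.8 and 811) had the same direction. CCP2, which the deposited product line calls a chloroplast envelope protein, was at 4.88 and 117 FPKM. The anion transporter NAR1.2 was at 2.33 and 49.3 FPKM. Also higher were SELW2 (0.670 and 23.2 FPKM), RSEP1, an intramembrane protease (18.1-fold), and MFT10, a transporter of the major facilitator superfamily (13.5-fold). Genes with lower values differed less. NSG1 was at 54.1 and 9.36 FPKM, the carotene hydroxylase gene CBH1 at 16.0 and 2.999, ELI5 at 5.69 and 0.918, the helicase gene HEL12 at 22.6 and 6.59, and PRX6, a thioredoxin-dependent peroxidase, at 30.3 and 9.08. GSP1, a homeobox factor of plus gametes, CLPS2, PRL10 and PRL6 were 4.56-fold, 3.29-fold, 3.05-fold and 2.97-fold lower, and MBI1 was at 7.36 and 2.38 FPKM.

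In the tetrapyrrole list, which holds the genes of chlorophyll synthesis, 4 of 22 genes were at least 2-fold lower after the wash and 0 higher, with a median of -0.19 (-0.49 under quantile normalization), below all 10000 random lists. The 4 genes were CHLH1, a magnesium chelatase subunit (138 and 56.9 FPKM), POR, which reduces protochlorophyllide (250 and 104), PBGD1 (252 and 111) and the chelatase regulator GUN4 (67.2 and 31.0). Cytosolic ribosomal protein genes had a median difference of 0.29 (0.07 under quantile normalization) with 0 of 74 at 2-fold, while plastid ribosomal protein genes had a median of 0.05, which became -0.22 under quantile normalization. Across all kept genes 1214 differed by 2-fold, 1065 higher and 149 lower. The split was 855 higher and 256 lower under quantile normalization, which moved the median of all genes by -0.11, and a pseudocount of 0.1 gave 1973 genes.

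**Figure D1:**
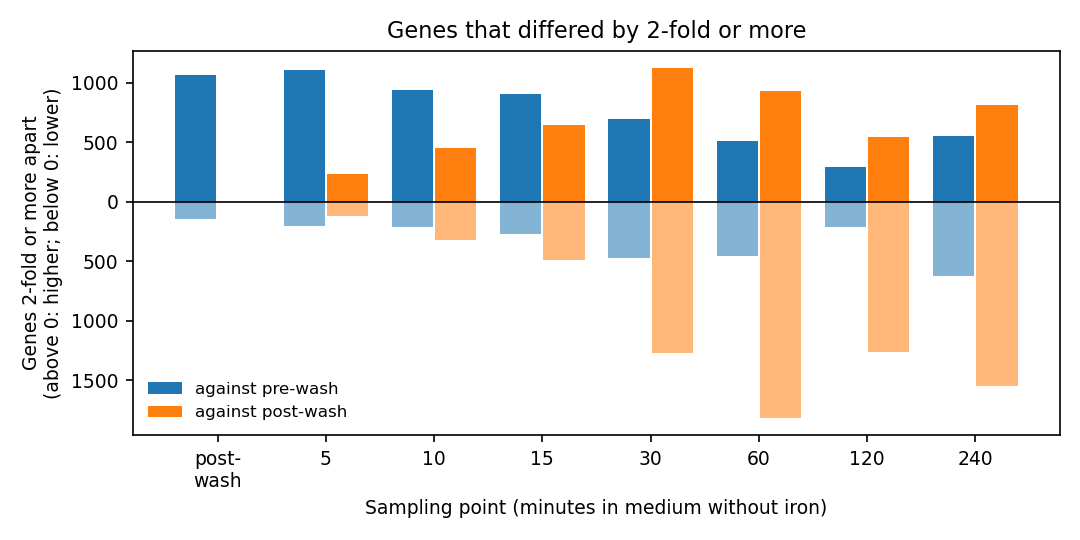
Number of genes that differed by 2-fold or more on the log2(FPKM + 1) scale at each sampling point (horizontal axis), against the pre-wash column (blue) and the post-wash column (orange), with higher genes above 0 and lower genes in a paler shade below it. Against pre-wash the total ran from 1306 genes at 5 min to 509 at 120 min, and against post-wash from 357 at 5 min to 2748 at 60 min.

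The later samples address how transcripts responded to transfer into medium without iron over time. No group moved into fresh medium with iron is among the samples, so time in fresh medium and absence of iron are not separated. All of these contrasts use the same post-wash column, so an error in that column enters each of them. The median against pre-wash is therefore also given for the gene lists. The CO2-concentrating mechanism, by which the alga raises CO2 around its carbon-fixing enzyme, differed further within 5 min. By then 10 of its 13 measured genes were at least 2-fold higher than post-wash and 0 lower, with a median of 1.51. At 10, 15 and 30 min 12 of 13 were higher, and the median was 2.04, 1.96 and 2.53. Against pre-wash the medians at 5, 10, 15 and 30 min were 2.21, 2.88, 2.88 and 3.48. The bicarbonate transporter HLA3 went from 2.59 FPKM post-wash to 20.6 at 5 min, the membrane protein LCI1 from 1.57 to 13.9, NAR1.2 from 49.3 to 248 and the mitochondrial carbonic anhydrase CAH5 from 12.8 to 42.1. The separate values of CAH4 and CAH5, which are near-identical, are uncertain, as are those within the pairs CCP1 and CCP2, LCID and LCIE, and LHCSR3.1 and LHCSR3.2.

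Of the 10 photoprotection genes, 4 were 2-fold higher than post-wash at 5 min and 7 at 30 min, and 0 were lower at either time. The medians were 0.91 (0.56 without the filter on low values) and 2.02, and 1.63 and 1.99 against pre-wash. LHCSR1, a light-harvesting-like protein that dissipates excess energy, was at 23.1 FPKM post-wash, 351 at 30 min and 501 at 60 min. LHCSR3.1 was at 2.74 and 43.9 FPKM (post-wash and 30 min), LHCSR3.2 at 6.49 and 54.3, and the early light-inducible protein gene ELI5 at 0.918 and 18.7. By 240 min the list had 4 members higher and 1 lower, and a median of 0.74 (0.76 against pre-wash).

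At 5 min 357 genes met the 2-fold rule, 235 higher and 122 lower. HLA3, LCI1 and CYG63 (0.797 to 8.47 FPKM) were the named genes that lay furthest above post-wash, and PHX15 (811 to 199), LCI35 (18.4 to 4.99) and VTE5 (9.02 to 2.23) those furthest below. At 10 min 453 genes were higher and 323 lower. LCI1 was then at 42.9 FPKM, the nucleoredoxin gene NRX3 at 25.96 against 1.503 post-wash, and LHCSR3.1 at 33.3. PHX15 was 9.95-fold, the metalloproteinase gene MMP7 5.59-fold and ZNJ3 4.32-fold lower. At 15 min 648 were higher and 486 lower, with LCI1 at 74.3 FPKM, NRX3 at 36.0 and CBH1 at 45.1, and with PHX15, GFY1 and MMP7 18.7-fold, 6.69-fold and 8.74-fold lower. With a pseudocount of 0.1 the totals at 5, 10 and 15 min were 847, 1496 and 2137, against 357, 776 and 1134.

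By 30 min 1122 genes were higher and 1274 lower than post-wash (2396 in all, and 3697 with a pseudocount of 0.1). LCI1 led at 341 FPKM, 218-fold above its post-wash value. Also among the 10 furthest above post-wash were CBH1 (30.3-fold), LHCSR1 (15.2-fold), NRX3 (20.8-fold), NRX2 (12.3-fold), HEL12 (14.6-fold), CAH5 (12.7-fold) and SULTR2, a sulfate transporter (12.0-fold). Furthest below lay the unnamed gene Cre13.g603550, from 783.5 to 4.32 FPKM. PHX15 went from 811 to 7.36 FPKM, GFY1 from 402 to 12.8, RSEP1 from 32.4 to 0.342, the iron hydrogenase HYDA2 from 62.9 to 1.94, TGL20 from 52.1 to 2.17 and the hexose transporter HPT1 on Cre10.g435650 from 19.0 to 0.522. CLPD1, a ClpD chaperone, and NAR1.3, a formate and nitrite transporter, were 21.8-fold and 14.3-fold lower, and SPO went from 204 to 15.7 FPKM.

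The fermentation and cilia lists, high directly after the wash, were followed over the course. Of the fermentation genes, 8 of 13 at 30 min and 11 at 60 min were at least 2-fold lower than post-wash, with medians of -1.11 and -2.34 and 0 higher. Against pre-wash the median was 1.84 at 5 min, -0.25 at 30 min, -1.04 at 60 min, with 8 genes 2-fold lower, and -0.24 at 240 min (-0.05 without the filter on low values and -0.41 with FPKM of 5 or more required). HYDG1 was at 3.91 FPKM at 60 min, below its pre-wash 16.8. Cilia genes were at least 2-fold higher than pre-wash in 223 of 328 cases at 5 min and in 28 at 30 min. The list median against pre-wash was 1.37 at 5 min and still 0.37 at 30 min (0.24 under quantile normalization). At 60 min 232 were 2-fold lower and 4 higher than post-wash (median -1.40), but only 8 were lower and 3 higher than pre-wash (median -0.32). FAP15, FAP165 and FAP138 were among those lower than post-wash, while FAP23 went the other way, from 42.4 to 336 FPKM. At 240 min the median of the cilia list against pre-wash was -0.03, or -0.06 under quantile normalization.

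Of 12 genes for acetate assimilation and the glyoxylate cycle, 10 were at least 2-fold lower than post-wash at 60 min and 0 higher, with a median of -2.14, below all 10000 random lists. ACK1, ACK2, PAT1 and PAT2 are named by both this list and the fermentation list, so the lower values of these lists are separate only in part. ICL1, PCK1, MAS1 and CIS2 are not among the shared genes. The isocitrate lyase gene ICL1 was at 1854 FPKM post-wash, 176 at 60 min and 931 at 240 min. PCK1, phosphoenolpyruvate carboxykinase, was at 475, 54.9 and 190 FPKM, the malate synthase gene MAS1 at 403, 48.1 and 278, and CIS2, a citrate synthase, at 287, 38.9 and 83.7. Against pre-wash 9 were lower at 60 min (median -1.78) and 2 at 240 min (median -0.82). In all 932 genes were higher and 1816 lower than post-wash at 60 min, led by LCI1 (355 FPKM), FRE1 (152) and IRT1 (27.1) and, on the lower side, by Cre08.g372200 (1789 to 3.65), PHX15 (3.18), PHX5 (0.665) and HYDG1.

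Iron assimilation genes followed a later course. Relative to post-wash, 0 of the 10 measured genes were 2-fold higher at 5 min, 1 at 10 min, 3 at 15 min, 7 at 30 min, 8 at 60 and 120 min, and 10 at 240 min. MSD3 alone was 2-fold lower, at 30 and 60 min. The median was 0.13 at 5 min (0.20 under quantile normalization and 0.21 with a pseudocount of 0.1), 0.41 at 15 min, 1.39 at 30 min, 2.09 at 120 min and 2.73 at 240 min, the last 3 above all 10000 random lists. Against pre-wash 1 gene was 2-fold higher at 5 min, 2 at 10 and 15 min and 7 at 30 min, and the median was 0.09 at 5 min (-0.15 under quantile normalization), 1.36 at 30 min and 1.94 at 120 min. The earliest members to meet the rule depend on the column they are set against. Against post-wash they were FEA2 at 10 min and FTR1 and TEF22 at 15 min. Against pre-wash IRT2 met it directly after the wash and FEA2 at 10 min, while FTR1 and TEF22, which were lower after the wash by 0.35 and 0.61 on the log2 scale, did so at 30 min.

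FRE1 (Cre04.g227400), a ferric-chelate reductase, was at 0.645 FPKM post-wash, 12.2 at 30 min and 913 at 240 min, the largest difference of any named gene against post-wash on the log2(FPKM + 1) scale. IRT1 (Cre12.g530400), a transporter of the ZIP family, was at 0.0663 FPKM post-wash, 3.55 at 30 min and 379 at 240 min. FEA1 (Cre12.g546550) and FEA2 (Cre12.g546600) encode Fe-assimilating proteins, and lie next to each other with TEF22 (Cre12.g546500) beside FEA1. FEA2 was at 62.6 FPKM post-wash and 2164 at 240 min, and FEA1, the most abundant member, at 1183 and 3930, with 4181 at 120 min. TEF22 was at 78.2 and 470 FPKM. The ferroxidase FOX1 (Cre09.g393150) was at 132 and 487 FPKM and its partner permease FTR1 (Cre03.g192050) at 74.0 and 719. IRT2 (Cre12.g530350), the neighbour of IRT1, was at 2.85 before the wash, 7.03 after it and 24.7 at 240 min. CGLD27 (Cre05.g237050) was at 10.2 post-wash and 80.4 at 240 min. MSD3 (Cre16.g676150), a manganese superoxide dismutase, had a course of its own, with 10.3 FPKM post-wash, 3.19 at 30 min, 3.25 at 60 min, 14.2 at 120 min and 67.2 at 240 min.

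**Figure D2:**
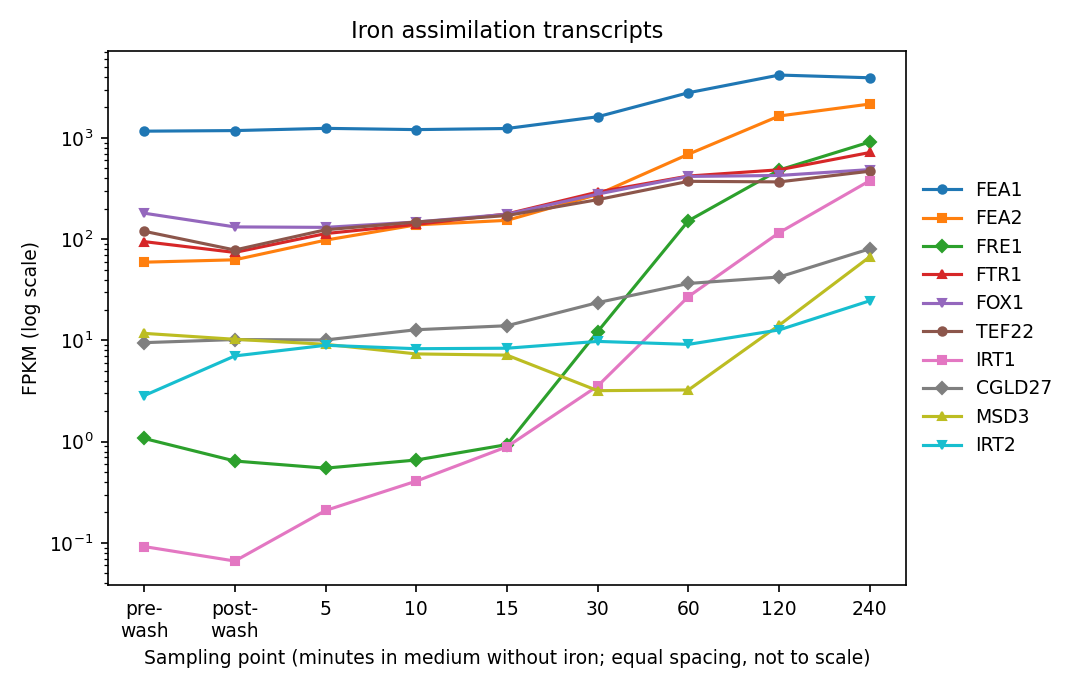
FPKM of the 10 measured iron assimilation genes (vertical axis, log scale) at the 9 sampling points (horizontal axis, equally spaced and not to scale), with 1 line per gene and each point the authors' combined value of 2 cultures. FRE1 and IRT1 lie near or below 1 FPKM until 15 min and reach 913 and 379 FPKM at 240 min, and MSD3 has its lowest value, 3.19 FPKM, at 30 min.

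Of 5 measured iron storage and handling genes, 2 were 2-fold higher than post-wash at 240 min and 0 lower (median 0.57, and 0.69 against pre-wash). These were the ferritins FER1, at 298 and 878 FPKM, and FER2, at 0.0933 and 3.47. In the iron-sulfur cluster list 2 of 8 genes were higher and 1 lower than post-wash at 30 min (median 0.70). Against pre-wash 1 was higher and 0 lower, and the median was 0.64, or 0.30 under quantile normalization. The entry NFU1 on Cre18.g748447 was at 8.07 and 54.8 FPKM, SUFD1 at 25.8 and 54.8, and ISCA2 at 17.2 and 3.14. At 240 min the median against post-wash was 0.00, or 0.28 under quantile normalization.

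At 120 min 547 genes were higher and 1265 lower than post-wash (1812 in all, and 2852 with a pseudocount of 0.1), and 509 differed from pre-wash. FRE1 (482 FPKM), LCI1 (539.5) and IRT1 (116) led the higher genes, and Cre08.g372200, PHX5, GOX17 (177 to 1.80) and HYDG1 the lower ones. The tetrapyrrole list had been lower at first. At 5, 10 and 15 min its medians were -0.26, -0.27 and -0.32 against post-wash and -0.45, -0.45 and -0.58 against pre-wash (-0.78, -0.76 and -0.89 under quantile normalization), each as deposited below all 10000 random lists. Then 7, 5 and 5 of 22 genes were 2-fold lower than pre-wash, and 0, 1 and 1 higher. The highest median was at 120 min, when 11 were 2-fold higher than post-wash and 0 lower (median 0.97), whereas only 1 was 2-fold higher than pre-wash and 0 lower (median 0.65). POR stood at 429 FPKM, PBGD1 at 436, CHLH1 at 217 and CTH1, a subunit of the cyclase that forms the isocyclic ring of chlorophyll, at 495.

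At 240 min 815 genes were higher and 1549 lower than post-wash, or 1071 and 1321 under quantile normalization. Behind FRE1 and IRT1 came LCI1 (682 FPKM), the carbonic anhydrase CAH1 (61.9 to 3286), FEA2, CAH5 (25.8-fold), CAH4 (24.0-fold), LHCSR3.1 (20.7-fold), LCI23 (0.324 to 19.3) and CCP1 (14.7-fold). In the CO2-concentrating list 8 of 13 genes were 2-fold higher than post-wash (median 2.64), after 10 at 60 min (median 1.67) and 7 at 120 min (median 1.57). Against pre-wash the median was 3.93 at both 60 and 120 min. Furthest below post-wash lay Cre08.g372200 (1789 to 4.14 FPKM), PHX15, HYDG1, GOX17 (79.7-fold), PHX5 (88.7-fold), the P-type cation ATPase gene ACA3 (347 to 11.3), HYDEF1 (37.5 to 0.651), RSEP1 (32.4 to 0.467), PHX4 (31.9 to 0.468), PNO1 (35.7 to 0.705) and GFY1 (19.7-fold).

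Of 21 light-harvesting genes, 10 were at least 2-fold higher than post-wash at 240 min and 0 lower (median 1.00). Against pre-wash the median was 1.01, or 0.63 under quantile normalization. At 60 min it was -0.28 against post-wash, or -0.06 under quantile normalization, and -0.29 against pre-wash. LHCBM4 was at 435 and 2235 FPKM (post-wash and 240 min), LHCBM8 at 29.5 and 115, LHCB7 at 4.66 and 19.9, and LHCBM2 at 2875 and 9833. Several LHCBM genes are near-identical, so reads could have been split between them. In the photosystem I list 0 of 15 genes reached 2-fold at 240 min. The median was 0.62, at percentile 99.98 of the random lists, and 0.67 against pre-wash (0.40 under quantile normalization), and PSAI, the member that differed most, was at 870 and 1549 FPKM.

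Of 47 measured antioxidant genes, 14 were 2-fold higher and 4 lower than post-wash at 240 min, and 14 higher and 1 lower than pre-wash. The medians of 0.54 and 0.66 were both above all 10000 random lists. The monodehydroascorbate reductase gene MDAR1 was at 15.9 and 190 FPKM, and PRX6 at 9.08 and 89.9. The entry PRX on Cre16.g663000 was at 3.97 and 0.0532. The heat shock and chaperone list had its highest median at 60 min, when 7 of 26 genes were 2-fold higher and 2 lower than post-wash (median 0.60, or 0.39 without the filter on low values, and 0.78 against pre-wash). HSP22F was at 277 FPKM post-wash and 715 at 60 min, and CLPB5 at 8.65 and 23.1, whereas CLPB1 was at 7.09 and 0.360 and HSP70H at 19.0 and 2.81. At 240 min CDJ3 (22.6 to 167 FPKM) and CDJ5 (31.5 to 132), which encode chloroplast DnaJ-type proteins, were the members furthest above post-wash.

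Set against the pre-wash cells, which do not depend on the post-wash column, 1172 genes differed at 240 min (551 higher, 621 lower, and 1782 in all with a pseudocount of 0.1). All 10 iron assimilation genes were 2-fold higher (median 2.82) and 12 of 13 CO2-concentrating genes (median 4.84). For the 6 CO2-concentrating genes without a near-identical copy on the list and without CAH1, the median was 2.23. LCI1 (0.390 to 682 FPKM), FRE1, IRT1, NAR1.2 (2.33 to 312), CAH1 (69.5 to 3286), CCP1 (51.8-fold), FEA2 (36.5-fold), CAH5 (37.5-fold), LHCSR3.1 (0.843 to 56.8 FPKM) and LHCSR3.2 (49.9-fold) differed most.

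Of 13 ribosome biogenesis genes, 9 were at least 2-fold lower at 240 min than pre-wash and 0 higher (median -1.49, below all 10000 random lists). Against pre-wash the median was -0.36 directly after the wash (-0.57 under quantile normalization), 0.43 at 30 min (0.19 under quantile normalization) and -0.72 at 120 min. The nucleolar protein genes NOP10 (194 and 59.2 FPKM, pre-wash and 240 min), NOP1 (572 and 179), NOP58 (198 and 63.1) and NOP14 (9.51 and 2.69) differed most. Ribosomal protein genes differed little in size, with 0 of 74 cytosolic and 0 of 33 plastid genes at 2-fold. In that order the medians were 0.05 (-0.19 under quantile normalization) and -0.18, at percentiles 60.96 and 0.12 of the random lists. Other named genes that were lower than pre-wash included GOX17 (7.46-fold), PWR3 (6.90-fold), PGM12 (122 to 23.8 FPKM), ACA3 (5.24-fold), the deoxyhypusine synthase gene DHS1 (46.9 to 9.33), HEL12 (5.41-fold), RRM11 (5.13-fold), the arginine methyltransferase gene PRMT1 (62.1 to 13.2), PHX15 (4.74-fold) and BIP2 (4.69-fold).

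**Figure D3:**
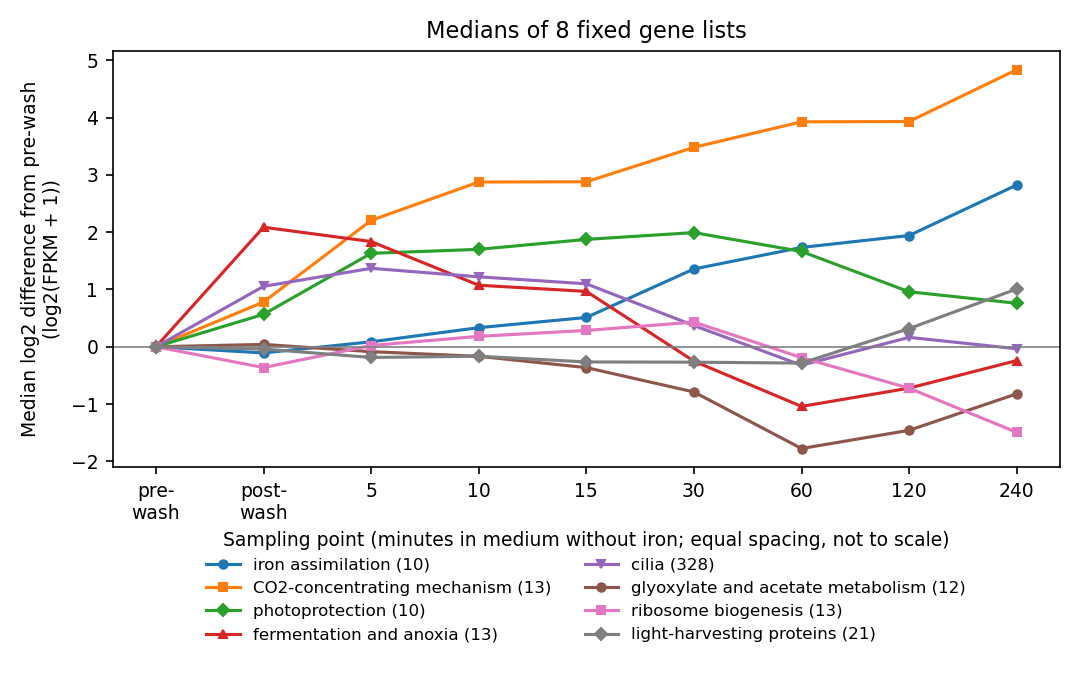
Median log2 difference from the pre-wash column (vertical axis, log2(FPKM + 1)) of 8 gene lists at the 9 sampling points (horizontal axis, equally spaced and not to scale), with the number of measured genes in brackets. The fermentation list is at 2.09 post-wash and -1.04 at 60 min, the CO2-concentrating list at 4.84 and the iron assimilation list at 2.82 at 240 min, and under quantile normalization the sign differs for iron assimilation at 5 min, acetate metabolism post-wash, and ribosome biogenesis at 5 and 10 min.

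Over the whole course after the wash, 5987 of 12580 genes (47.6%) differed by 2-fold or more between their highest and lowest value. Among 1144 genes with at least a 4-fold range and FPKM of 5 or more, 404 had their highest value post-wash, 200 at 5 min, 210 at 30 min and 166 at 240 min, and 19 to 72 at each of the other times. The lowest value fell at 60 min in 306 genes and at 240 min in 324. Neighbouring columns were closest from 10 to 15 min, with 7 genes at 2-fold, and 352, 410, 407 and 216 genes differed over the later steps to 30, 60, 120 and 240 min. Of the 216 medians of 24 lists in 9 contrasts, 123 lay outside the central 95% of the random lists, against 5% for lists of unrelated genes. The contrasts share columns and some lists share genes, so these medians are not separate outcomes.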

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

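Alternatives were chosen before the data were examined, except that they were applied to counts of 2-fold differences in place of the planned tests. No paired analysis was possible because the deposited columns combine both cultures and carry no replicate numbers. For the same reason the replicate block and the fits leaving out each library were not run. The filters, quantile normalization and median-of-ratios scaling kept the count of each contrast within 1.5 times the reported one. A pseudocount of 0.1 gave 1973 genes for the wash, 847, 1496, 2137, 3697 and 2852 at 5, 10, 15, 30 and 120 min against post-wash, and 1782 for 240 min against pre-wash. The smaller pseudocount by construction enlarges the log2 differences of genes with low FPKM. Between 123 and 126 of 216 list medians lay outside the central 95% of random lists under the alternatives.

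Of 199 differences of named genes, 0 changed sign under the alternatives in which they were measured. The filters and the smaller pseudocount cannot change the sign of a single gene's difference. Only quantile normalization and median-of-ratios scaling could therefore have changed any of these signs. With a pseudocount of 0.1, 92 moved by more than 0.168 on the log2 scale, the spread between the 10 and 15 min columns, and 53 did so under quantile normalization. List medians outside the central range changed sign in 3 cases. Without the filter on low values, the median of the gamete and nitrogen list at 240 min against post-wash was -0.0014 in place of 0.71, and that of the sulfur and phosphorus list at 120 min was 0.33 in place of -0.96. Both lists then hold more, weakly expressed members. Under quantile normalization the plastid ribosomal protein list was at -0.22 after the wash in place of 0.05. As deposited, its 0.05 was already at percentile 0.62 of the random lists, whose median was 0.15. The median of all genes also moved there, by -0.11, and by -0.13, -0.12 and -0.10 at 5, 10 and 15 min against pre-wash. The cause of the change of sign was not tested further. Depth is unknown, so values below 1 FPKM limit what can be said of each gene for which one is printed.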

Other observations

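The explanations weighed here were all tested after the results had been seen. Of 5 measured zinc-responsive genes, 3 were at least 2-fold higher than post-wash at 5 and 10 min, and 4 at 15 min, with medians of 1.24, 1.41 and 1.11, and of 1.75, 2.21 and 2.30 against pre-wash. At 15 min ZRT1, a ZIP-type transporter, was at 11.4 FPKM against 1.06 post-wash, ZRT5 at 72.9 against 15.4 and ZRT2 at 72.0 against 32.8. At 240 min these genes were at 0.651, 20.6 and 15.1 FPKM. In the copper-responsive list 2 of 8 genes were higher after the wash and 0 lower (median 0.61), the copper transporters CTR2 (8.35 and 58.4 FPKM) and CTR1 (12.1 and 31.8). At 60 min CTR2 was at 12.6 and CTR1 at 12.9 FPKM, and the list median was -0.71 against post-wash and -0.09 against pre-wash (-0.20 under quantile normalization). At 10, 15 and 30 min 1 gene of this list was 2-fold higher than post-wash and 0 lower, and 4 were higher than pre-wash and 0 lower (medians of 1.03, 1.00 and 0.86 against pre-wash). CYC6, a cytochrome made by copper-deficient cells, was at 0.0844 FPKM pre-wash and 5.17 at 30 min.

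The sulfur and phosphorus list went both ways at 60 min, with 3 of 7 genes higher and 2 lower than post-wash and a median of -0.55, or 0.35 without the filter on low values. Against pre-wash at the same time 3 were higher and 0 lower, and the median had the opposite sign, 0.81 (0.63 under quantile normalization). The sulfate transporter SULTR2 was at 11.0 FPKM post-wash, 132 at 30 min and 17.1 at 240 min, and SLT1, another sulfur-related transporter, at 1.23, 17.4 and 5.83. In the gamete and nitrogen starvation list 2 of 5 genes were higher and 2 lower after the wash (median -0.19, or -0.87 with FPKM of 5 or more required and -0.005 without a filter). GAS30 was at 0.171 and 2.55 FPKM and GAS28 at 103 and 223, while NSG1 and GSP1 were lower. Of 24 DNA replication and cell cycle genes, 1 was higher and 2 lower at 10 min against post-wash (median -0.46, and -0.36 against pre-wash), namely E2F1 (1.62 to 5.35 FPKM), RIR2 (27.2 to 9.56) and CYCD2 (48.3 to 23.3). Only 14 of 113 matched histone genes, which have many near-identical copies, passed the filter on low values. These 14 had a median of -0.42 (-0.67 with a pseudocount of 0.1) at 240 min against pre-wash, with 0 at 2-fold. Without the filter the list median was -0.14. None of 29 proteasome and autophagy genes reached 2-fold at 60 min, although their median of 0.57 was at percentile 99.95 of the random lists and was 0.63 against pre-wash, and RPN3 went from 19.6 to 35.4 FPKM.

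Fermentation transcripts were high directly after the wash. Scaling between the columns was tested by recomputing the list median after quantile normalization, which moved the median of all genes by -0.11. The list median was then 1.99 (quartiles 0.08 and 2.43). With so small a shift of all genes, the list median could not have fallen far. The value therefore shows only that a scale difference of that size is not the whole of it. A lasting effect of missing iron, acting alone, would have kept the list above its pre-wash level. Its median at 60 min against pre-wash was instead -1.04 (quartiles -1.51 and -0.67). An opposite change over the same time could hide such an effect, since time in fresh medium and absence of iron are not separated. ACK1, ACK2, PAT1 and PAT2 are also on the acetate list, whose median was then -1.78 against pre-wash. Handling of the cells, with pelleting and possibly low oxygen in the pellet, is a candidate explanation for the 8 of 13 genes that were 2-fold higher. The labels list the same spin for the pre-wash samples, and of the handling steps only the washes are not listed for them. Handling stays open beside an effect of iron removal, either brief or offset later by another change, and these cannot be told apart. No group washed into medium with iron is among the 18 samples.

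The CO2-concentrating list had a median of 0.78 directly after the wash, with 4 of 13 genes 2-fold higher, and of 2.21 at 5 min and 4.84 at 240 min against pre-wash. As a consequence of the response of the iron assimilation genes they would follow these. At 5 min against post-wash, however, their median exceeded that of the iron list by 1.38. By then 10 of 13 against 0 of 10 genes were 2-fold higher. This covers the early difference only. Against post-wash the CO2-concentrating median was 1.57 at 120 min and 2.64 at 240 min, with the iron list at 2.09 and 2.73. For this later part, a consequence of the iron response stays open. Reads shared between near-identical copies on the list do not account for the 6 members without such a copy. CAH1, which has the relative CAH2, was left out of these as well. These 6 had a median of 2.23 at 240 min against pre-wash (quartiles 1.65 and 5.56), against 4.84 for all 13 genes. The size of the list median thus rests in part on the members left out, for which shared reads stay open. Close copies elsewhere in the genome were not searched for. A changed CO2 supply on transfer to fresh medium may contribute to the 12 of 13 genes that were 2-fold higher at 240 min. No group moved into fresh medium with iron is among the samples, so it cannot be told apart from an effect of iron deprivation on the same genes.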
